A study of Synechocystis sp. PCC 6803 with 6 samples.

How the data were processed

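RNA was sequenced from axenic cultures of the glucose-tolerant substrain GT-L of the cyanobacterium Synechocystis, a unicellular photosynthetic bacterium. There were 3 control libraries and 3 libraries treated with an aliphatic alcohol, hexan-1-ol. The labels' protocols name BG-11 medium with 20 mM HEPES at pH 7.5, light of 100 µE, air with 1.6% CO2 and an Ion Torrent total RNA kit. The dose and the length of the treatment are not given in the sources used here. Each library pooled 3 technical replicates, per the labels, and a control and a treated library with the same number name the same 3 culture vessels out of 9.

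Per the submitters' processing notes, BWA 0.7.17, SAMtools 1.9 and DESeq2 were used. The genome build, the annotation, the read counter, the handling of strand and the DESeq2 version and settings are not given in the sources used here. The authors' deposited table has 3468 genes, 1 line per gene, and no column per library. Per the file headers it holds, for each gene, a mean signal (read counts divided by size factors and averaged over all libraries), a log2 fold change with its standard error, a Wald score, a p-value and a Benjamini-Hochberg adjusted p-value. The deposited score equalled the log2 fold change divided by its standard error for all 3468 genes. The deposited adjusted p-values equalled a Benjamini-Hochberg adjustment over the 1727 genes that have one, to within rounding. Of the other genes, 1734 had a p but no adjusted p and lay under a mean of 4.17, and 7 had no p. Standard errors rose to 0.981 near a mean of 0.93 and were lower again, 0.668, at the smallest mean, which is the form that a prior pulling folds towards 0 gives, so folds of genes with few reads are understated. The header does not name the direction of the fold. A positive fold is taken as higher with hexan-1-ol, because the authors used DESeq2, which takes the alphabetically first group as the reference unless told otherwise, and the labels name a control and a treatment. Every direction below rests on this reading.

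The design written before the data were examined provided for a table of comparisons without values per library, in which case no model is refitted: the fold changes, standard errors and adjusted p-values are the authors' own, and the threshold is an adjusted p under 0.05. In addition, 26 gene lists were fixed by locus tag before the data were examined. They cover chaperones, proteases, sigma factors and stress regulators, fatty acid desaturases, fatty acid and lipid synthesis, cold-inducible genes, photosystem I and II, the phycobilisome, electron carriers, NDH-1, ATP synthase, photoprotection, oxidative stress, carbon concentration, nitrogen, phosphate and iron acquisition, efflux, ribosomal proteins, pigment synthesis, sugar catabolism, compatible solutes, pili, hydrogenase and alcohol metabolism. They hold 383 locus tags, of which 381 are in the table. The deposited table does not pair tags with symbols, and 0 of its tags matched the RefSeq gene table of 3347 genes, which uses other locus tags. Gene symbols and functions are therefore those written into the lists beforehand from general knowledge of the nomenclature of this strain, and genes on no list are not given a name.

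Each list was tested with limma's cameraPR (limma 3.58.1, R 4.3.3) on the authors' Wald score over the 1727 genes with an adjusted p, with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. This is a test across genes, which are not independent replicates, and an estimated correlation needs values per library. Presets of 0.05 and 0.1, a rank-based version and 10000 random lists matched on 20 classes of mean signal were the alternatives for lists. For the calls per gene, the alternatives were no filter on low means, a mean of at least 50, an adjusted p under 0.01, a log2 change of at least 1 and folds centred on their median, each recomputed from the authors' values. On simulated scores for 1727 genes, the test recovered 8.2% of lists shifted by 0.5, 72.6% of those shifted by 1 and 100% of those shifted by 2 units of the score. The simulated scores were independent and standard normal, and only lists with at least 10 tested members were shifted. The authors' scores spread more widely (standard deviation of the central part 1.29) and may be correlated. The recovery rates therefore do not carry over to those scores or to shorter lists. The genes named are the 10 largest rises and the 10 largest falls in fold past the threshold with a mean of at least 10, up to 4 members of each list with the smallest adjusted p, and all chaperones, desaturases and sigma factors. Of the 20 genes with the largest changes, 14 are on no list, and only 2 that rose and 2 that fell are given by identifier. The rule's further condition, that all treated libraries lie on one side of the controls, applied only to values per library and was not used. No other column of per-sample values was used.

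The table also holds depth. A gene with 1 read in 1 library has a mean that is fixed by that library's size factor, and 6 such values gave the 6 size factors. Each mean up to 50 was then searched for whole numbers of reads per library whose scaled average equals it, to a relative tolerance of 3e-15. All 3241 of 3241 such genes had exactly 1 solution, and on simulated reads for 296 genes the search returned the true reads for 100%. The 227 genes above that mean were not searched. The recovered libraries carry no label. They are numbered by falling size factor, are matched to no sample, and enter no comparison between groups. The tables and permutations were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.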

Results

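The series asked how the transcriptome of Synechocystis responds to hexan-1-ol, an aliphatic alcohol, with 3 treated libraries against 3 control libraries. Sequencing was shallow. The mean normalised read counts of all 3468 genes in the authors' deposited table sum to 70193 reads per library, the median gene has a mean of 4.16, and 72.7% of genes have a mean under 10. The 3 most abundant genes hold 11.6% of the sum. Reads recovered from the means gave 6 size factors of 2.11, 1.82, 0.985, 0.716, 0.662 and 0.662, so that the depth of the libraries differs by up to 3.18 times. Within these reads, libraries 3 and 4 differed by no more than sampling noise over 1172 genes with at least 10 reads in the pair (chi-square per degree of freedom 1.05, p = 0.106). For libraries 5 and 6 the chi-square per degree of freedom was 1.21 (chi-square test, p = 1.2e-05), and for the other 13 pairs it was 2.69 to 6.51. Libraries 5 and 6 were thus also much closer to each other than those 13 pairs. The authors' deposited table gives one result over the 6 libraries, so neither libraries 3 and 4 nor libraries 5 and 6 were counted as 1 sample. Its p-values measure only the spread between the 6 libraries, which may be technical. The model formula is not given, so whether those p-values allow for the vessels shared by control and treated libraries is unknown. The table's header does not name the direction of the fold, and every rise or fall rests on reading a positive fold as higher with hexan-1-ol.

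With hexan-1-ol, 8 of 14 chaperone genes, 4 of 14 protease genes and 5 of 10 genes of the photoprotection list were higher. The sigma factor genes sigB and sigD were higher too, and the largest rise on these lists was 101-fold in the authors' deposited table. Transcripts for 3 enzymes of pigment metabolism and for apcA and apcB, 2 subunits of the light-harvesting antenna's core, fell, with log2 changes between -1.32 and -0.99 in the authors' deposited table. The authors' deposited table calls 133 of 1727 genes at an adjusted p (DESeq2, Benjamini-Hochberg) under 0.05, of which 111 were higher and 22 lower with hexan-1-ol. If the fold were coded the other way, 111 would be lower and 22 higher, and the larger changes would be the falls. As read here, rises were also larger: in the authors' deposited table the median called rise is 5.53-fold and the largest 111-fold, against a median called fall of 2.80-fold and a largest of 4.95-fold. A log2 change of at least 4 was reached by 17 genes that rose and by 0 that fell. The median log2 fold change of all tested genes was -0.04. Among genes with a mean of at least 10, a pair on no list led the rises in the authors' deposited table, sll0846 (log2 fold change 6.80, SE 0.71) and sll0528 (6.79, SE 0.48), and slr0423 (-2.31, SE 0.67) and ssl2250 (-2.03, SE 0.70) were among the largest falls.

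Most of the chaperone genes rose. In the authors' deposited table the small heat shock protein gene hspA (sll1514), which binds unfolding proteins and membranes, was 101-fold higher (log2 fold change 6.66, SE 0.49, adjusted p = 2.73e-39). The disaggregase gene clpB1 (slr1641) was 40.8-fold higher there (log2 5.35, SE 0.46), the co-chaperone gene dnaJ (slr0093) 20.7-fold (4.37, SE 0.50) and htpG (sll0430), the bacterial HSP90, 11.9-fold (3.58, SE 0.42). The HSP70 gene dnaK2 (sll0170) rose 5.05-fold, and the chaperonin genes groES (slr2075), groEL2 (sll0416) and groEL1 (slr2076) rose 2.65-fold, 2.42-fold and 2.18-fold in the authors' deposited table (SE 0.35 to 0.40 on the log2 scale). Of 14 chaperone genes, 8 rose and 1 fell, and 9 rose and 2 fell when adjusted over the list alone. The gene that fell was clpB2 (slr0156), the second ClpB gene, at -1.79 (SE 0.59, adjusted p = 0.0372) in the authors' deposited table. The 5 members not called there were dnaK1 (sll0058) at -0.12 (SE 0.44), dnaK3 (sll1932) at -0.03 (SE 0.42), the other dnaJ genes sll0897 at 1.21 (SE 0.46) and sll1933 at 0.09 (SE 0.76), and grpE (sll0057), the nucleotide exchange factor of HSP70, at -0.89 (SE 0.40). Without the filter on low means, the adjusted p was 0.0727 for clpB2 and 0.0636 for groEL1, from the p-values of the authors' deposited table. The list as a whole stood above other genes (cameraPR on the authors' score, adjusted p = 7.2e-13, and 2.1e-06 with a correlation of 0.1). With less weight on the largest scores the evidence was weaker. The rank-based test gave an adjusted p of 0.020, and the list median against random lists gave 0.0065.

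Of 14 protease genes, 4 rose and 0 fell, the same counts when adjusted over the list alone. In the authors' deposited table htrA (slr1204), a Deg-type serine protease, was 39.3-fold higher (log2 5.30, SE 0.46, adjusted p = 6.27e-28), and ctpA (slr0008), which processes the D1 protein of photosystem II, 8.56-fold higher (3.10, SE 0.39). The thylakoid protease genes ftsH2 (slr0228) and ftsH3 (slr1604) rose 4.12-fold and 3.19-fold in the authors' deposited table (log2 2.04 and 1.67, SE 0.39 and 0.38). The other Deg genes did not pass, with hhoA (sll1679) at -0.68 (SE 0.63) and hhoB (sll1427) at 0.48 (SE 0.57) in the authors' deposited table, nor did the Clp protease genes, for example clpC (sll0020) at 0.49 (SE 0.39). The list stood above other genes by cameraPR (adjusted p = 0.00057). The list's median log2 fold change of 0.34 lay at percentile 88.9 of random lists (adjusted p = 0.38), and the rank-based test gave an adjusted p of 0.056.

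**Figure D1:**
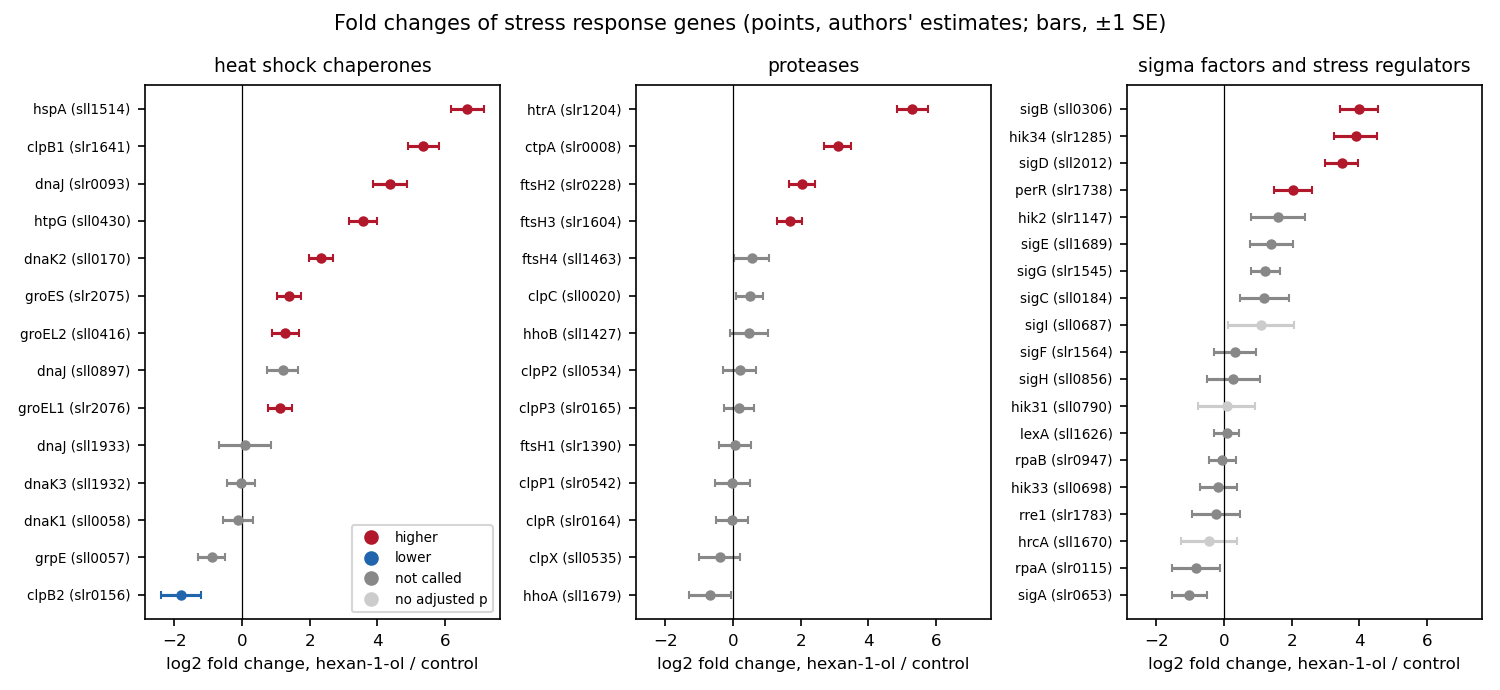
Log2 fold change (x axis, hexan-1-ol over control) of each chaperone, protease and regulator gene (rows) as estimated by the authors, with bars of 1 standard error. Red genes were higher and blue lower at an adjusted p under 0.05, dark grey genes did not pass and light grey genes have no adjusted p; hspA, clpB1 and htrA lie above 5, and clpB2 is the 1 gene called lower.

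Of 16 tested regulators, 4 rose and 0 fell, with 5 rising when adjusted over the list alone. In the authors' deposited table sigB (sll0306) and sigD (sll2012), sigma factors that redirect RNA polymerase under stress, were 15.8-fold and 11.2-fold higher (log2 3.98, SE 0.57, and 3.48, SE 0.48). The histidine kinase gene hik34 (slr1285), known for its part in heat regulation, was 14.8-fold higher (3.89, SE 0.63) and the peroxide regulator gene perR (slr1738) 4.09-fold higher (2.03, SE 0.56) in the authors' deposited table. The remaining sigma factor genes were not called there: sigA (slr0653), the principal one, was at -1.03 (SE 0.51), sigC (sll0184) at 1.19 (SE 0.72), sigE (sll1689) at 1.40 (SE 0.63), sigF (slr1564) at 0.33 (SE 0.62), sigG (slr1545) at 1.22 (SE 0.43, adjusted p = 0.0532) and sigH (sll0856) at 0.27 (SE 0.78). The gene sigI (sll0687) has a mean of 0.989 and no adjusted p in the authors' deposited table. The list test gave an adjusted p of 0.0029, which became 0.098 with a correlation of 0.1 and 0.056 with ranks.

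Within the fixed lists, which hold 43 of the 133 called genes, photoprotection genes formed the other large group of rises. Of 10 tested members 5 rose and 0 fell, and 6 of 13 in the table rose when adjusted over the list alone. The 5 include nblA2, which is on the list although its product acts in phycobilisome breakdown. In the authors' deposited table the high light inducible genes hliA (ssl2542), hliB (ssr2595) and hliC (ssl1633), whose products bind chlorophyll and carotenoid under light stress, were 25.2-fold, 17.8-fold and 7.11-fold higher (log2 4.65, 4.15 and 2.83, SE 0.53, 0.67 and 0.63). The orange carotenoid protein gene ocp (slr1963), which quenches the antenna, was 9.69-fold higher (3.28, SE 0.42) and nblA2 (ssl0453), an adaptor for phycobilisome breakdown, 6.90-fold higher (2.79, SE 0.84) in the authors' deposited table. The fourth family gene hliD (ssr1789) was at 0.41 (SE 0.66) and did not pass in the authors' deposited table. The list stood above other genes (adjusted p = 3.1e-07, and 0.00029 with a correlation of 0.1).

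Some genes of pigment synthesis and the phycobilisome fell. Of 12 tested genes on the list of chlorophyll and heme synthesis 3 fell and 0 rose, and 4 fell when adjusted over the list alone. Among the 3, ho1 encodes an enzyme of heme breakdown rather than of either synthesis. In the authors' deposited table chlA1 (sll1214), the oxygen-dependent cyclase of chlorophyll synthesis, fell by 1.32 (SE 0.39) on the log2 scale, the heme oxygenase gene ho1 (sll1184) fell by 1.30 (SE 0.39) and chlP (sll1091), a geranylgeranyl reductase gene, fell by 1.18 (SE 0.35), with adjusted p-values of 0.0134, 0.0166 and 0.0133. The list median was -0.95, below other genes (adjusted p = 0.00063, 0.033 with a correlation of 0.1, and 0.063 among genes with a mean of at least 50). Of 12 tested phycobilisome genes, the allophycocyanin subunit genes apcA (slr2067) and apcB (slr1986) fell by 1.19 and 0.99 (SE 0.32 each) in the authors' deposited table, and 10 did not pass, among them the core genes apcC (-0.68, SE 0.40), apcD (-0.23, SE 0.39), apcE (-0.57, SE 0.33) and apcF (-0.71, SE 0.38); the count was also 2 when adjusted over the list alone. The phycocyanin genes cpcA (sll1578) and cpcB (sll1577) were at -0.32 (SE 0.31) and -0.51 (SE 0.30) in the authors' deposited table. The phycobilisome list was below other genes at an adjusted p of 0.014, which became 0.055 with a correlation of 0.05.

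Neither list of photosystem genes was called by cameraPR (adjusted p = 0.19 for photosystem I and 0.59 for photosystem II). Of 12 photosystem I genes, 0 passed in the authors' deposited table (DESeq2; 1 at an unadjusted p under 0.05), where psaA (slr1834) and psaB (slr1835), the 2 most abundant transcripts, were at -0.22 and -0.17 (SE 0.40 each). Of 24 tested photosystem II genes, psbA3 (sll1867), which encodes D1, rose 2.16-fold (log2 1.11, SE 0.35) and psbE (ssr3451), a cytochrome subunit gene, fell by 1.21 (SE 0.39) in the authors' deposited table. Adjusted over the list alone, the counts were also 1 and 1. The near-identical psbA2 (slr1311) was at 0.48 (SE 0.32) there, and reads of the psbA copies can be split between them by the alignment, so the values of both are uncertain. The same holds for psbD1 (sll0849, 0.13, SE 0.36) and psbD2 (slr0927, 0.69, SE 0.34) in the authors' deposited table. The list adjusted p-values were 0.40 for electron carriers, 0.68 for NDH-1 and 0.41 for ATP synthase. Of 11 tested electron carrier genes and 10 ATP synthase genes 0 passed DESeq2's test, and 1 in each had an unadjusted p under 0.05. Of 17 tested NDH-1 genes ndhD2 (slr1291) was called, at 6.81-fold higher (log2 2.77, SE 0.50) in the authors' deposited table, as it was when adjusted over the list alone.

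Of 3 tested fatty acid desaturase genes, desD (sll0262) fell by 2.29 (SE 0.72, adjusted p = 0.0251) in the authors' deposited table at a mean of 8.38 reads. There desA (slr1350) was at -0.61 (SE 0.66), desC (sll0541) at 0.46 (SE 0.40), and desB (sll1441), at -0.06 (SE 0.82), has a mean of 3.66 and no adjusted p. Changes of the size of these standard errors were not detectable at this depth. Adjusted over the list alone 1 desaturase gene fell, and the list adjusted p was 0.43. Of 17 tested genes of fatty acid and lipid synthesis, accA (sll0728), an acetyl-CoA carboxylase subunit gene, fell by 1.94 (SE 0.67) and the reductase gene fabG (slr0886) fell by 1.74 (SE 0.58) in the authors' deposited table, and 3 fell when adjusted over the list alone. Without the filter on low means, the adjusted p was 0.0939 for accA and 0.0783 for fabG, from the p-values of the authors' deposited table. The list median was -0.78 (adjusted p = 0.015), but the call was lost with a correlation of 0.05 (adjusted p = 0.076). Cold-inducible genes split: ndhD2 and rbp3 (slr0193, an RNA-binding protein gene, 1.18, SE 0.35) rose and desD fell in the authors' deposited table, while the RNA helicase gene crhR (slr0083) was at 0.92 (SE 0.37). When adjusted over the list alone 3 cold-inducible genes rose and 1 fell, and the list was not called (adjusted p = 0.46).

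In nitrogen metabolism, gifB (sll1515) and gifA (ssl1911), which encode inhibitors of glutamine synthetase, were 17.1-fold and 10.8-fold higher in the authors' deposited table (log2 4.10, SE 0.50, and 3.44, SE 0.67). The glutamate synthase gene gltS (sll1499) rose 2.14-fold (1.10, SE 0.38) and nirA (slr0898), nitrite reductase, fell by 1.32 (SE 0.43) in the authors' deposited table. Of 20 tested nitrogen genes 3 rose and 1 fell (3 and 2 when adjusted over the list alone). Their median was -0.45, at percentile 0.4 of random lists (adjusted p = 0.030), whereas cameraPR gave an adjusted p of 0.46. Single members rose in 4 other lists: the superoxide dismutase gene sodB (slr1516) 4.02-fold (log2 2.01, SE 0.49), the alcohol dehydrogenase gene adhA (slr1192) 4.63-fold (2.21, SE 0.58), the bicarbonate transporter gene sbtA (slr1512) 4.26-fold (2.09, SE 0.70) and the pilin gene pilA1 (sll1694) 2.31-fold (1.21, SE 0.38) in the authors' deposited table. Adjusted over the list alone, each of these lists also had 1 rise except carbon concentration, which had 0. The list adjusted p-values were 0.68 for oxidative stress, 0.43 for alcohol metabolism, 0.66 for carbon concentration and 0.41 for pili.

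Of 50 ribosomal protein genes, rps1b (slr1984) fell by 1.48 (SE 0.47) in the authors' deposited table, 0 passed when adjusted over the list alone, and the list adjusted p was 0.11. No member was called among 15 tested genes of sugar catabolism, 9 of iron, 7 of phosphate and 6 of efflux, 3 of hydrogenase or 2 of compatible solutes, and their list adjusted p-values were 0.33, 0.33, 0.97, 0.88, 0.99 and 0.41. For efflux the median (-0.03) and the mean (0.16) differ in sign, and for phosphate the median was 0.08 with a test direction of lower. At an unadjusted p under 0.05 in DESeq2's test, these lists had 1, 2, 0, 1, 0 and 0 genes. Without the filter on low means the calls of apcB, psbE, gltS, nirA, sbtA, rps1b and ssl2250 were also lost, with adjusted p-values of 0.0522 to 0.0939. The median standard error over tested genes was 0.61 on the log2 scale, and the smallest called changes were 1.10 for a rise and -0.99 for a fall in the authors' deposited table.

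**Figure D2:**
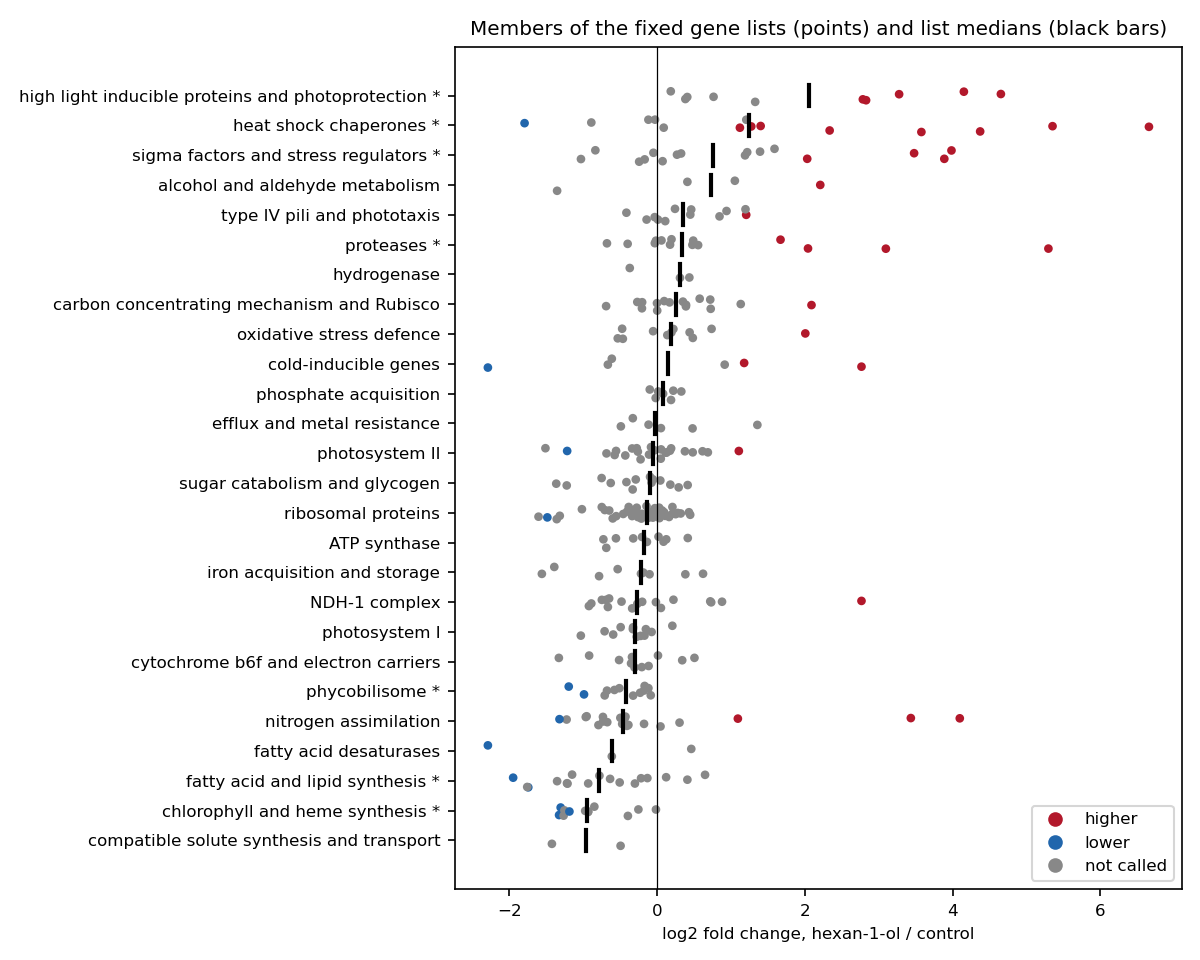
Log2 fold change (x axis, hexan-1-ol over control) of the members of the 26 fixed lists that have an adjusted p (points, offset vertically for display), with the list median as a black bar. Red and blue points were called higher and lower, and an asterisk marks the 7 lists with a cameraPR adjusted p under 0.05, 4 above and 3 below other genes.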

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

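All tests in this part were chosen after the values were seen. Of the 7 genes that have no p in the authors' deposited table, and so enter no comparison, 4 are on the phosphate acquisition list, namely phoA (sll0654), nucH (sll0656), pstS2 (slr1247) and pstC2 (slr1248). Only 5 phosphate genes are among the 352 genes at least as abundant as the rarest of the 7, and Fisher's exact test gives a two-sided p of 2.76e-07. That p treats genes as independent and is too small, since the 4 form 2 pairs with close identifiers. DESeq2, the authors' tool, leaves out a p for genes with an extreme count in a library.

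The reads recovered from the means show the spread in pstC2 and a like one in phosphate genes that were tested and not called. For pstC2 (slr1248) the 6 libraries, in order of falling size factor, hold 260, 265, 3, 3, 0 and 1 reads, and for pstA2 (slr1249) 60, 56, 1, 2, 0 and 0. For pstC1 (sll0681) they hold 137, 119, 9, 7, 8 and 8 reads. The log2 folds of the 12 phosphate genes in the authors' deposited table are at most 0.33 in size, each smaller than its standard error. The prior pulls such folds towards 0 but need not remove a large one. For example, hliB (ssr2595) kept 4.15 at SE 0.67 there, against 0.08 for pstC1 (SE 0.66). The phosphate folds thus show no rise or fall, but with standard errors of 0.66 to 0.98 they do not exclude one. As 3 libraries were treated, hexan-1-ol as the whole cause would put the third highest library with the 2 highest. The gap between the second and the third highest was taken over the 8 phosphate genes with recovered reads. Its median was 30.6% of a gene's normalised reads (range 15.4% to 43.0%), so these genes show 2 high libraries, not 3. In 10000 random lists matched on mean the median gap was at most 12.2%. The list was chosen because members lacked a p, as genes with an extreme count do, which makes a large gap likely. The random lists therefore cannot decide about hexan-1-ol. For depth, the median share of a gene's normalised reads in its 2 highest libraries was 78.7% for these 8 genes. In such lists, which also treat genes as independent, it was at most 70.1%. As the list was chosen for members without a p, this comparison alone cannot decide about depth either. The 2 highest libraries are 1 and 2, the deepest, for 8 of the 8 genes, but for only 9.80% of other genes. That argues against depth acting on all genes alike. A difference between cultures, for example in phosphate supply or age, stays open as a hypothesis. It was not tested, because the recovered libraries were not assigned to groups or vessels from their values.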

How the results depend on the processing

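No paired analysis was possible because the deposited table has no column per library and the recovered reads carry no replicate number. The recovered reads were not assigned to groups from their values, by choice, so these were not run: leaving out a library, another normalization, an edgeR or DESeq2 fit, removal of abundant genes, an estimated correlation, fry and counts over splits of the libraries. Against 133 called genes (111 higher, 22 lower, 83.5% higher), an adjusted p under 0.01 left 75 (73 and 2, 97.3% higher). A mean of at least 50, with p-values adjusted again over 222 genes, gave 47 (38 and 9), of which 44 were among the 133; fewer genes are tested. No filter on low counts, with adjustment over 3461 genes, gave 102, of which 101 were among the 133, with 9 lower and 91.2% higher. Requiring a log2 change of at least 1 gave 132, and centring the folds on their median, added after seeing the data, gave 134, of which 129 were among the 133. Of the genes named or eligible to be named, 14 lost their call without the filter, among them clpB2, groEL1, psbE, fabG, accA, nirA, gltS, sbtA, apcB, rps1b and ssl2250. Of the same genes, centring ended 3 calls, accA and ssl2250 among them, and added sigG. Of the 26 lists 7 were called; 4 were with a correlation of 0.1 (chaperones, photoprotection, proteases and pigment synthesis), and 2 of the 16 lists with at least 3 members above a mean of 50, where fewer genes are tested. The other settings called 5 to 7 lists. For lists, the settings of a mean of at least 50, all genes with a p and scores capped at 4 were not planned. No call turned in direction, but lists without a call did: phosphate (lower) was higher with ranks, over all genes with a p and with scores capped at 4, and at a mean of at least 50 carbon concentration turned lower and nitrogen higher. A gene near a mean of 4 has little room to fall, which limits calls of falls.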

Other observations

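Centring of the folds was chosen after the calls had been seen; what each test should show was written before its outcome was measured. Called genes tended to carry consecutive identifiers. Among 818 pairs of tested genes with consecutive numbers and the same prefix, 25 pairs were called in 1 direction and 0 in opposite directions, against a median of 5 and a maximum of 15 in 10000 permutations within classes of mean signal (p = 0.0001, one-sided, the smallest they can give). These pairs hold 42 of the 133 called genes. Chance placement is argued against, and a candidate explanation is that such genes lie side by side and are transcribed together. Reads counted to overlapping neighbours stay open as well, since no coordinates were used.

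Calls were skewed towards 1 direction, 111 of 133, which are rises if a positive fold means higher with hexan-1-ol and falls if it is coded the other way. A scaling offset between the groups stays open. With folds centred on their median 86.6% of calls were positive (exact binomial interval 79.6% to 91.8%), but the median was already at -0.04, so centring, although foreseen as its test, moved too little to decide. Harder detection of falls, as the direction is read here, may add to the skew but does not account for all of it. Among 475 genes whose geometric mean of both group levels is at least 20, which treats rises and falls alike, 48 of 60 calls, 80.0% (67.7% to 89.2%), were positive. The intervals treat genes as independent, which genes of 1 operon are not. A skewed response to hexan-1-ol itself stays open as a hypothesis, with a direction that rests on the same reading.

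Reads per library, in order of falling size factor, were 233, 5, 3, 2, 58 and 60 for hliA (ssl2542), 146, 3, 3, 1, 21 and 19 for hik34 (slr1285), and 63, 5, 1, 0, 13 and 17 for gifA (ssl1911). For desD (sll0262) they were 6, 12, 18, 14, 2 and 0, and for sbtA (slr1512) 16, 1, 10, 4, 14 and 39. The metal exporter genes coaT and ziaA also differed between libraries. Not scaled for depth, reads were 247, 63, 6, 6, 7 and 5 for coaT (slr0797), which has no p. For ziaA (slr0798) they were 40, 51, 2, 4, 0 and 2. Normalised reads ran from 6.09 to 117 for coaT and from 0 to 28.0 for ziaA. Of the other efflux genes some were more even, with normalised reads of 12.6 to 19.5 for acrB (slr2131) and 19.5 to 32.5 for tolC (slr1270). Others were not, for example copM (sll0788) with 9.77 to 70.8. The spread of the efflux list as a whole was not tested. The iron-stress gene isiA (sll0247) has a standard error of 0.98 at a mean of 96.2 in the authors' deposited table, where the median gene with a mean of at least 50 has 0.39.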
